A study of Mus musculus with 16 samples.

How the data were processed

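Cells of mouse tail epidermis were sorted by flow cytometry from K14CREER/Rosa-SmoM2-YFP mice, in which tamoxifen switches on SmoM2 in keratin 14 expressing cells, from the same mice carrying floxed β-catenin alleles, and, for the bulge and outer root sheath, from K19CREERT2/Rosa-SmoM2-YFP mice. Per the labels' protocols, RNA was amplified and labelled with a 3′ in vitro transcription kit and hybridised to Affymetrix mouse expression arrays. The authors deposited 1 table of 45101 probe sets in 16 arrays. Its values are on a log2 scale, read from their range, and the deposited arrays have medians between 5.38 and 5.53. The submitters' processing notes name R 2.14.0, and the methods of background correction, normalization and probe set summary are not given in the sources used here. The number of arrays limits the precision. The labels do not say whether replicates are separate mice or pools, so p-values measure the spread between these samples. Some arrays had both Xist and Y-linked signal, such as 4-week SmoM2 replicate 3 (12.52 and 6.02) and β-catenin loss replicate 2 (12.43 and 6.91). IFE control replicate 1 had 11.11 and 3.41. These values argue that such samples hold cells of both sexes, and so of more than 1 mouse. For the other arrays this stays open.

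Groups were taken from the sample labels: IFE control (n = 3, untreated), IFE SmoM2 at 3 days (n = 1), 1 week (n = 3), 4 weeks (n = 3) and 10 weeks (n = 2), IFE SmoM2 with β-catenin loss at 4 weeks (n = 2), bulge control (n = 1) and bulge SmoM2 at 4 weeks (n = 1). The source label of the bulge control names SmoM2-positive cells while its treatment is given as none, and the array was used as the control that its title gives. Groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined.

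Probe sets were matched to genes with the array annotation. Of the 45101 probe sets, 34958 had 1 gene, 932 had several and 9211 had none, and 64 were array controls. Of those with 1 gene, 34754 matched the gene table by identifier and 0 were renamed. Each of the 18194 genes was read from its probe set of highest mean. Genes were tested if their signal lay above the 40th percentile of the array in at least 2 of the 16 arrays, which left 14286. Some fixed list genes are not reported here. No further normalization was applied in the main analysis.

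Differences were tested with limma 3.58.1 in R 4.3.3: a linear model of group means over the 14 IFE arrays, contrasts between groups, and empirical Bayes moderation (total degrees of freedom 11.6). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and genes that changed at least 2-fold were counted besides. The comparisons were 3 days, 1 week, 4 weeks, 10 weeks and β-catenin loss against control, 4 weeks against 1 week, 10 weeks against 4 weeks, and β-catenin loss against SmoM2 alone at 4 weeks. The lone array at 3 days was assumed to vary like the other groups. The bulge arrays were compared by their difference alone, and list medians were set against 10000 random lists of genes of like signal.

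For 22 fixed gene lists, camera was run with a preset inter-gene correlation of 0.01 as the main test, with camera at an estimated correlation and fry beside it, each adjusted by Benjamini-Hochberg over the lists of a comparison. The lists were hedgehog pathway and targets, Wnt/β-catenin targets, Wnt ligands and receptors, embryonic hair placode and germ, bulge stem cell markers, basal epidermis and hemidesmosome, interfollicular differentiation, hair follicle keratins and differentiation, cell cycle, Notch pathway, BMP and TGF-β pathway, wound and barrier stress, immediate-early and dissociation stress, interferon response, sterol and fatty acid synthesis, leukocytes, melanocytes, Merkel cells, dermal fibroblasts, endothelial cells, sebaceous gland and skeletal muscle. Several share members: 5 of the 16 hedgehog genes, 13 of the 23 placode genes and 10 of the 21 bulge genes tested are also in other lists. The genes chosen at 10 weeks for the test of β-catenin loss had to change at least 2-fold at an adjusted p under 0.05, and the camera p-values of those that rose and those that fell were adjusted over both sets, a step added after the results were seen.

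The named genes followed a rule. Per comparison they were the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, up to 4 members of each list with the largest change past the threshold or else the 2 of lowest adjusted p, and a fixed set that includes Gli1, Ptch1, Hhip, Smo, Ctnnb1, Axin2, Lef1, Lgr5, Lhx2, Sox9, Shh, Cux1, Runx1, Cdh3, Krt14, Krt1, Krt10, Krt17 and Mki67. For the bulge pair they were that set and the 5 largest differences each way. Ccnd2, Fzd1 and Tcf7l1 at 4 weeks, Cxcr4 at 10 weeks, Gli2, Mycn, Wif1, Krt36 and Krt84 in comparisons where the rule does not name them, Cd34, S100a8, and the genes behind counts of 5 or fewer that lie outside the rule were chosen after their values were seen.

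The analysis was tested on simulated data with the same design, in which 200 of 14286 genes were changed. For 4 weeks against control it recovered 31.3%, 85.1% and 98.5% of genes changed by 1, 2 and 4 log2 units, with 6 false calls. For 10 weeks against control the shares were 29.9%, 77.6% and 93.9% with 7 false calls, for 1 week 34.3%, 83.6% and 98.5% with 11, and for 3 days 7.46%, 67.2% and 92.4% with 4. For β-catenin loss against SmoM2 alone they were 25.4%, 79.1% and 98.5% with 11 false calls, and against control 28.4%, 82.1% and 98.5% with 8. For 4 weeks against 1 week they were 38.8%, 79.1% and 97.0% with 9, and for 10 against 4 weeks 28.4%, 71.6% and 97.0% with 10. The simulated noise was independent between genes and between arrays. It left out the pairing of arrays described next, so the shares may differ in the real data.

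Whether replicate numbers pair the arrays was checked from the residuals of the group means. In the control, 1-week and 4-week groups, arrays of the same number correlated at 0.343 to 0.696 across genes (9 pairs) and arrays of different numbers at −0.532 to −0.0021 (18 pairs). With the 10-week and β-catenin loss arrays, the same numbers gave −0.184 to 0.125 (14 pairs) and the experiment numbers in the descriptions −0.184 to 0.178 (13 pairs), so these groups were not taken as paired. Residuals cancel within a group for each gene, so the values of different numbers follow in part from those of the same number. In groups of 2 arrays the values come in pairs of opposite sign. The pair counts therefore overstate the number of independent values. The main model has no block, and the block was run as an alternative. Overlap between comparisons that share controls was set against 100 simulated data sets without change. Simulations with independent changes and with paired arrays, and the choice of genes against 2 controls, were added after the results were seen.

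The alternatives fixed in this way were a further quantile normalization, no filter and a stricter filter on dim probe sets (60th percentile), the mean of a gene's probe sets, a model of only the groups compared, empirical Bayes with trend and robust options, blocks by replicate number and by experiment number, array weights, and leaving out each replicate. After the data were seen, a block in the 9 paired arrays alone, a covariate of Y-linked signal and a run without sex chromosome genes were added. Xist and Y-linked signals differed between arrays of a group and between groups.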

Results

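The arrays measured how gene expression in basal cells of the mouse tail interfollicular epidermis (IFE) differed after induced expression of SmoM2, a constitutively active form of the hedgehog signal transducer Smoothened used to model basal cell carcinoma. Sorted cells were compared 3 days (n = 1), 1 week (n = 3), 4 weeks (n = 3) and 10 weeks (n = 2) after tamoxifen with cells of untreated mice of the same genotype (n = 3). Changes credited to SmoM2 here cannot be told apart from effects of tamoxifen, time since it, or sorting SmoM2-positive cells. Sex was not balanced between the groups either, and the main model does not adjust for it. The mean log2 signal of Y-linked genes was 3.41, 8.18 and 3.43 in the controls and 8.10 and 8.15 at 10 weeks. At 4 weeks it was 8.41, 7.58 and 6.02 with SmoM2 alone and 3.39 and 6.91 with β-catenin loss. A further group carried SmoM2 together with loss of β-catenin for 4 weeks (n = 2), which asks how far the SmoM2 expression changes need β-catenin. No group had β-catenin loss without SmoM2, so such a need cannot be told apart from an effect of the loss by itself. Cells of the hair follicle bulge were measured in a single control array and a single SmoM2 array. Values are log2 array signals as deposited, changes are differences of log2 means ± SE, and adjusted p-values are from limma over 14286 genes.

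Ctnnb1, the gene that encodes β-catenin and was targeted for deletion, had a log2 signal of 12.85 ± 0.12 (SD, n = 2) in the β-catenin loss group, with 12.76 in replicate 1 and 12.93 in replicate 2. The SmoM2 group at 4 weeks had 13.37 ± 0.24 (SD, n = 3; 13.65, 13.21 and 13.26) and the controls 12.86 ± 0.16 (SD, n = 3; 13.04, 12.76 and 12.77). The signal was 12.69 at 3 days, 13.19 ± 0.20 (SD) at 1 week, 13.07 ± 0.06 (SD) at 10 weeks, 13.45 in the bulge control and 13.42 in bulge SmoM2 cells. The difference of −0.52 ± 0.21 between loss and SmoM2 alone did not pass (adjusted p = 0.215), and the other Ctnnb1 probe sets differed by −0.20 and 0.63. Where the probes lie relative to the deleted exons was not checked, so these signals do not check the deletion.

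On the first principal component, with 26.9% of the variance, the controls lay between −39.7 and −34.8 and the 4-week SmoM2 arrays between 21.7 and 48.0. Replicate 3 at 1 week lay at −30.2, near the controls, while replicates 1 and 2 lay at −6.12 and 32.0. The β-catenin loss arrays lay at −27.4 and −14.6. The arrays at 10 weeks were the most alike of any group, with a median absolute difference of 0.173 log2 between them against 0.405 to 0.612 for the closest arrays of the other groups. The labels do not say whether they come from separate mice, and the p-values at 10 weeks take them as independent.

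**Figure D1:**
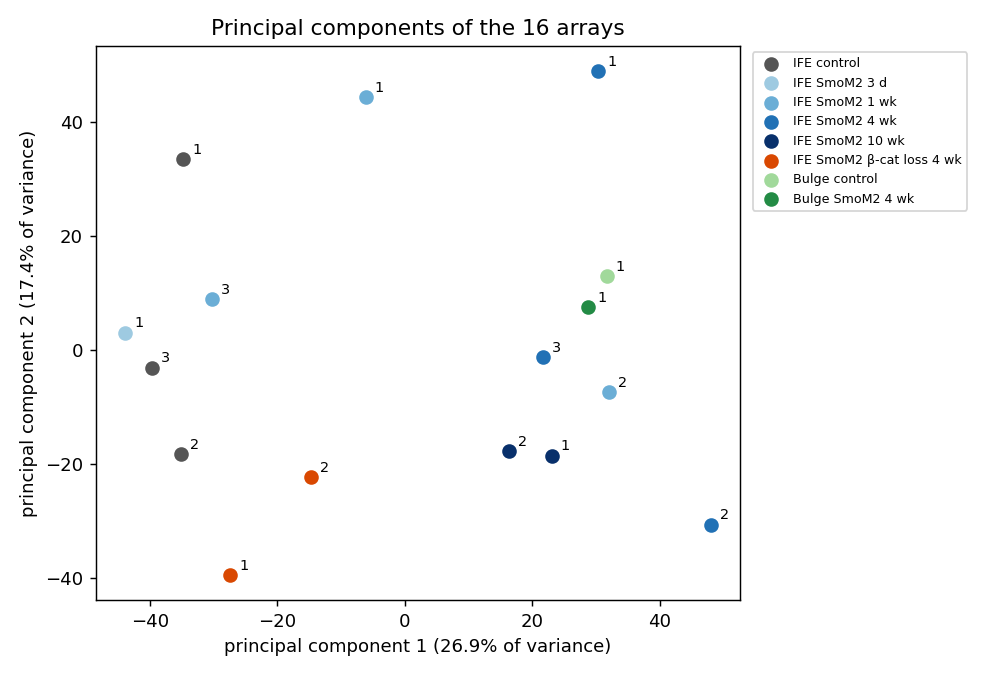
Principal components 1 (x axis, 26.9% of variance) and 2 (y axis, 17.4% of variance) of the 16 arrays, computed over the genes tested. Each point is an array, coloured by group and numbered by replicate, and replicate 3 at 1 week lies at −30.2 on the x axis, next to the controls.

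At 4 weeks the direct targets of hedgehog signalling stood among the clearest rises. Gli1, a transcription factor induced by the pathway, rose by 4.91 ± 0.54 (adjusted p = 0.00587; n = 3 and 3), from 5.54 to 10.44 on the log2 scale. Ptch1, the hedgehog receptor and a target gene, rose by 4.09 ± 0.47 (adjusted p = 0.00587), and the pathway effector Gli2 by 3.58 ± 0.49 (adjusted p = 0.00884). All 3 SmoM2 arrays lay above all 3 controls for Gli1 and Ptch1. Lhx2, a transcription factor of hair placodes and follicle stem cells, rose by 4.48 ± 0.68 (adjusted p = 0.0101), and Lgr5, an R-spondin receptor of follicle stem cells, by 3.88 ± 0.70 (adjusted p = 0.02).

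At 4 weeks the adhesion molecule Nrcam rose by 5.69 ± 1.10, the fibril-associated collagen Col14a1 by 5.37, the protease-like Prss35 by 4.81, the fibrillar collagen Col27a1 by 4.26 and the mesenchymal cadherin Cdh11 by 4.16. Smaller rises were found for the follicle regulator Tbx1 (2.90), the growth factor Bmp6 (2.64, adjusted p = 0.0499), the follicle and stress keratin Krt17 (2.07), the Wnt receptors Fzd3 (1.95) and Fzd1 (1.10), the bulge transcription factor Tcf7l1 (1.60), and Lef1, the transcription factor that carries the Wnt signal (1.37 ± 0.19, adjusted p = 0.00884). Smo itself rose by 1.29 ± 0.27 (adjusted p = 0.028), and whether its probe set also reads the transgene was not tested.

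Of the genes that fell at 4 weeks, the hair-type keratins Krt84 and Krt36, present at 12.58 and 13.05 in control tail epidermis, changed by −4.16 ± 0.74 and −4.16 ± 0.88 (adjusted p = 0.02 and 0.0308). The suprabasal keratin Krt2 changed by −3.83, the cornification transglutaminase Tgm3 by −3.37 ± 0.50 (adjusted p = 0.0101), the metallothionein Mt4 of differentiating epithelia by −3.99, and the phosphodiesterase Gdpd2 by −4.18. Ugt8a, a galactosyltransferase, changed by −3.90, the small proteoglycan Ogn by −3.80 and the sialic acid lyase Npl by −3.77. Among Wnt ligands, Wnt3 (−2.65), Wnt4 (−1.37) and Wnt10a (−1.16) fell, as did the Wnt target Ascl2 (−1.86) and the cyclin Ccnd2 (−1.17). Several values did not pass, among them the hedgehog target Hhip (3.77, adjusted p = 0.0699), the Wnt antagonist Wif1 (4.94, 0.0658), Mycn (3.77, 0.0546), Cux1 (1.10, 0.0715), the basal keratin Krt14 (−0.86, 0.0736), the suprabasal keratins Krt10 (−0.94, 0.0781) and Krt1 (−1.34, 0.155), the Wnt target Axin2 (−0.53, 0.503), the proliferation marker Mki67 (−0.34, 0.867) and Shh (0.04, 0.977).

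Over the 14286 genes, 463 changed at 4 weeks, 349 higher and 114 lower, and 431 of them changed at least 2-fold. Replicate numbers paired the control, 1-week and 4-week arrays, and with the replicate number as a block 873 genes changed, 461 of them shared with the 463. Krt14 passed under the block (adjusted p = 0.0471) and the proteoglycan Dcn, which rose by 2.59 without it, did not (0.0526). The count rested on most libraries: it was 132 without control replicate 1, 13 without control replicate 2, 49 without control replicate 3, 139 without 4-week replicate 1 and 237 without 4-week replicate 2. Over all 18 alternatives, adjusted p ranged from 0.00102 to 0.0353 for Gli1, from 0.0017 to 0.0353 for Ptch1 and from 0.00588 to 0.0451 for Lef1, and from 0.00946 to 0.106 for Krt36.

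**Figure D2:**
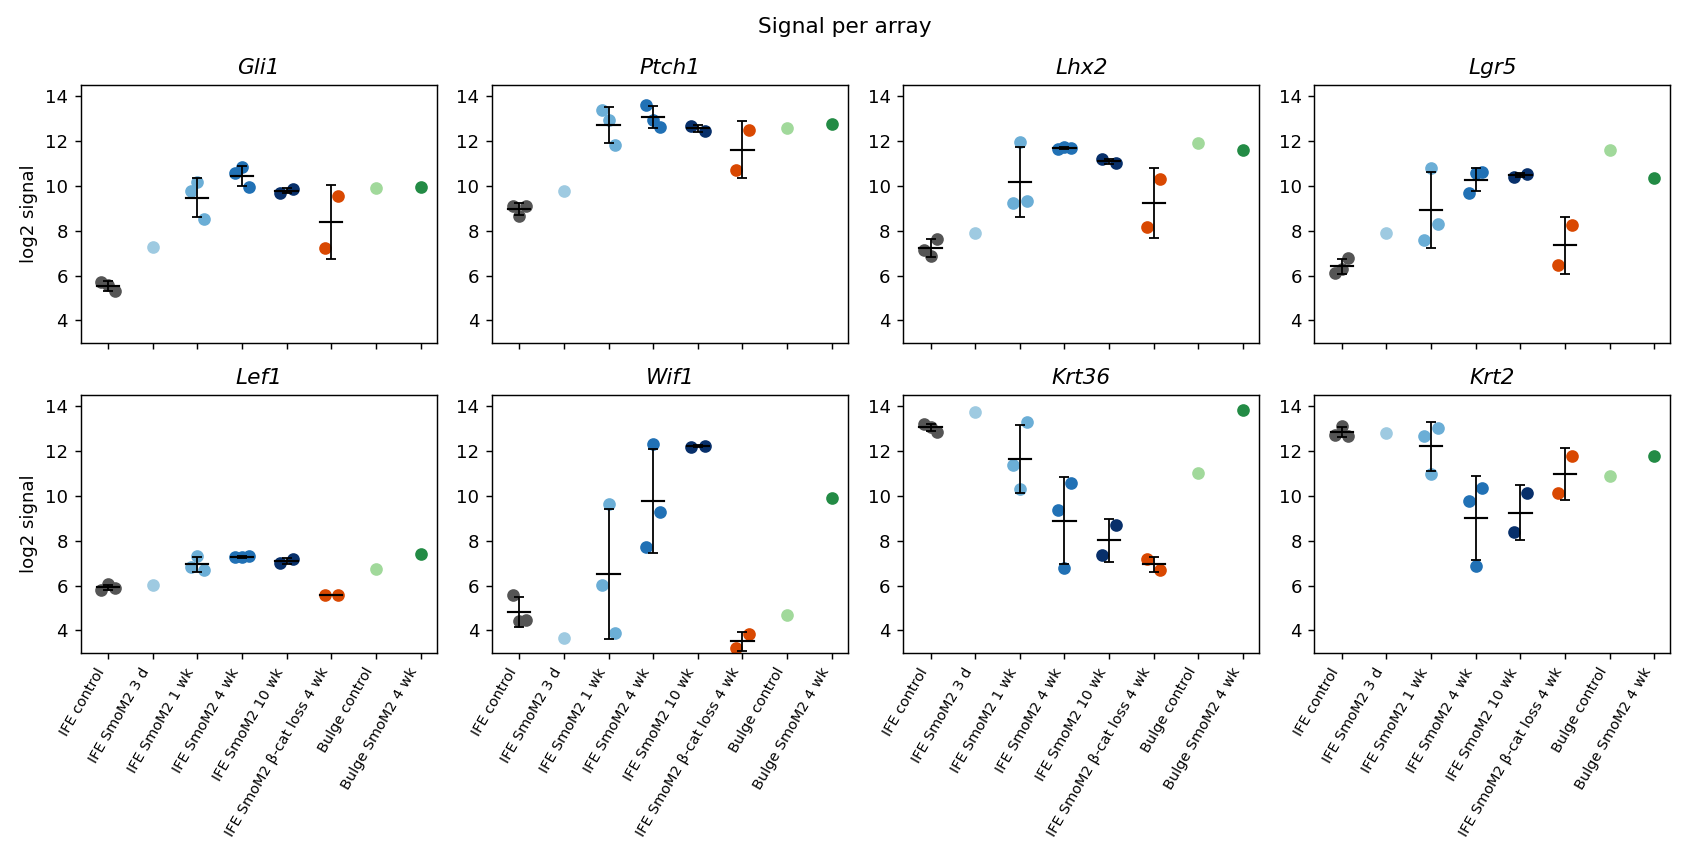
Log2 signal (y axis) of 8 genes in each group of arrays (x axis), with a point per array, a line at the mean and an error bar of 1 SD where a group has replicates. Gli1 lay at 5.54 in the controls and 10.44 in SmoM2 cells at 4 weeks, and Wif1 at 12.21 at 10 weeks and 3.53 under β-catenin loss.

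Among lists of genes fixed before the data were examined, 4 of the 16 hedgehog pathway genes tested rose at 4 weeks and 1 fell (8 and 2 adjusted over the list alone), with a median change of 0.71 (camera adjusted p = 8.3e-06). Bulge stem cell markers had a median of 1.14, with 5 of 21 risen (11 adjusted over the list alone; adjusted p = 6.3e-07). Embryonic hair placode and germ genes had a median of 0.89, with 5 risen and 1 fallen of 23 (9 and 2 adjusted over the list alone; adjusted p = 8.9e-05). In the BMP and TGF-β pathway Bmp6 rose out of 19 genes (7 rose and 2 fell adjusted over the list alone), with a median of 0.53 (adjusted p = 4.5e-04). The basal epidermis and hemidesmosome list had a median of −0.28, with no member past the threshold over all genes and 4 of 13 lower adjusted over the list alone (adjusted p = 0.00348). Interfollicular differentiation genes had a median of −0.36, with Krt2 and Tgm3 fallen of 27 (1 higher and 3 lower adjusted over the list alone; adjusted p = 0.013). None of these 6 calls held with an estimated correlation, where the lowest adjusted p at 4 weeks was 0.0583 for the placode and BMP lists, and the hedgehog list had 0.171, the bulge markers 0.201, the basal list 0.288 and the differentiation list 0.636.

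Markers of other cells moved as well at 4 weeks. The melanocyte list had a median of −1.57 (adjusted p = 0.00348, or 0.551 with an estimated correlation) and the sebaceous gland list −0.99 (0.00348, or 0.458), with all 7 sebaceous genes lower. The dermal fibroblast list had a median of 0.60 (0.0125, or 0.201), with Dcn risen. Cell cycle genes had a median of −0.44 (0.00348, or 0.751), and immediate-early and dissociation stress genes 0.65 (0.0104, or 0.636). The remaining lists did not pass at 4 weeks: Wnt ligands and receptors −0.04 (0.937; 2 rose and 3 fell, 6 and 5 adjusted over the list alone), hair follicle keratins −0.10 (0.482; 1 rose and 2 fell, 4 and 5 adjusted over the list alone), Notch pathway 0.14 (0.35), wound and barrier stress genes 0.37 (0.403), interferon response −0.20 (0.714), sterol and fatty acid synthesis 0.10 (0.391), T cells, Langerhans cells and other leukocytes 0.23 (0.35), Merkel cells 0.21 (0.799), endothelial cells −0.31 (0.344) and skeletal muscle −0.06 (0.751). Wnt/β-catenin targets had a median of −0.02 but a mean of 0.35 and an upward test (0.714), with Lef1 and Lgr5 risen and Ascl2 fallen (3 and 2 adjusted over the list alone).

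At 1 week the same hedgehog genes were higher in value, and no gene passed over all genes. Gli1 was higher by 3.94 ± 0.54 (adjusted p = 0.072), Ptch1 by 3.75 ± 0.47 (0.072) and Gli2 by 3.18 (0.072), with the 3 SmoM2 arrays above the 3 controls for Gli1 and Ptch1. Lhx2 differed by 2.96 (0.339), Lgr5 by 2.498 (0.474), Dcn by 3.40 (0.168), Krt17 by 1.82 (0.333) and Lef1 by 1.03 (0.168), and Hhip, by 2.08, did not pass either. The limma count was 0 of 14286, with 677 genes at an unadjusted p under 0.05. With replicate number as a block, Gli1 (adjusted p = 0.0336) and the lipoprotein receptor Scarb1 (1.69, adjusted p = 0.0336), named because the count was so small, passed. Over 18 alternatives the adjusted p of Gli1 ranged from 0.00735 to 0.333 and that of Ptch1 from 0.00608 to 0.425. Without 1-week replicate 3, the array near the controls, 50 genes changed, 42 of them higher. Without control replicate 3 a single gene, Stk33, passed (−2.67).

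The hedgehog list at 1 week had a median of 0.58, with 5 of 16 genes higher adjusted over the list alone and 0 over all genes (camera adjusted p = 8.2e-10). The placode list had a median of 0.61 (5 higher and 1 lower adjusted over the list alone; adjusted p = 3.8e-06) and the BMP and TGF-β list 0.31 (1 higher adjusted over the list alone; 0.00114). These 3 calls held with an estimated correlation (adjusted p = 0.0418 for each) but not with the block added to it (0.126 for each). Bulge markers had a median of 0.57 (8.7e-08, or 0.182 with an estimated correlation), with 5 of 21 higher adjusted over the list alone. All 29 cell cycle genes had positive changes, with a median of 0.36 (0.00306, or 0.807 with an estimated correlation), and all 9 melanocyte genes had negative changes, with a median of −1.11 (1.4e-04, or 0.312). Leukocyte genes had a median of 0.44 (0.00537, or 0.423) and dermal fibroblast genes 0.31 (0.0106, or 0.182), while the basal epidermis list had −0.14 (8.9e-04, or 0.187) and sterol and fatty acid synthesis 0.42 (5.8e-04, or 0.236).

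At 3 days the single SmoM2 array had a Gli1 signal of 7.28 against 5.54 in the controls, a difference of 1.74 ± 0.76. Lgr5 differed by 1.47 and Ptch1 by 0.81, and Lhx2 by 0.69. No gene passed, with 222 at an unadjusted p under 0.05 and a lowest adjusted p of 0.549, in a limma fit that assumes that the lone array varies like the others. Of the hedgehog list 6 of 16 genes were higher, and its median was −0.11 while its mean was 0.11. A single array does not separate its own deviation from an effect of 3 days in a list test either. The lists under the threshold were basal epidermis (median −0.34, camera adjusted p = 1.4e-04), sterol and fatty acid synthesis (0.53, 2.4e-04), melanocytes (−0.80, 0.0125), leukocytes (−0.29, 0.015) and interferon response (−0.54, 0.0471), none of them with an estimated correlation (lowest 0.493). In simulated data this design recovered 67.2% of genes changed by 2 log2 units and 7.46% of those changed by 1.

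At 10 weeks the hedgehog genes stood at levels like those at 4 weeks. Gli1 was 4.24 ± 0.60 above control (adjusted p = 0.016; n = 2 and 3), Ptch1 3.61 ± 0.53 (0.0166), Gli2 3.37 (0.0213), Lhx2 3.89 (0.0462), Lgr5 4.07 (0.0449), Krt17 2.41 (0.0428), Fzd1 1.33 (0.0455) and Lef1 1.19 (0.0319). The largest rise was in Wif1, a secreted Wnt antagonist, by 7.38 ± 1.45 (adjusted p = 0.0475). The secreted antagonists Fst and Grem1 were 3.48 ± 0.51 (0.0166) and 3.46 ± 0.59 (0.0267) above control. The chemokine receptor Cxcr4 rose by 3.38, the antimicrobial peptide Defb3 by 4.35 ± 0.45 (0.0106), the transglutaminase Tgm5 by 4.33, the actin-binding Synpo2 by 4.78, the protocadherin Pcdh20 by 4.28, Cyyr1 by 4.16 and the predicted gene Gm5084 by 4.76.

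The lowest changes at 10 weeks were in Krt84 (−5.25 ± 0.83, adjusted p = 0.0187) and Krt36 (−5.03 ± 0.98, adjusted p = 0.0475). Tgm2, a transglutaminase, changed by −3.26, the imprinted regulator Plagl1 by −3.22, Hemgn by −2.56, the semaphorin coreceptor Nrp1 by −2.47, the neurotrophin receptor Ntrk2 by −2.39, the exchange factor Rasgrf2 by −2.14 and Ascl2 by −1.72. In all, 100 genes changed, 81 higher and 19 lower. With array weights 845 were higher and 700 lower, and with only the groups compared 499 and 239. Both 10-week arrays were needed: 0 genes changed without replicate 1, and without replicate 2 only Defb3 did. The count was 45 without control replicate 1, 18 without control replicate 2 and 20 without control replicate 3. Over 16 alternatives the adjusted p of Gli1 at 10 weeks ranged from 9.9e-05 to 0.242 and that of Wif1 from 2.2e-04 to 0.496.

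Among the lists at 10 weeks, bulge markers had a median of 1.57, with 4 of 21 risen (15 higher and 2 lower adjusted over the list alone; camera adjusted p = 4.3e-10, or 0.117 with an estimated correlation). The hedgehog list had a median of 0.71 with 3 of 16 risen (7 and 2 adjusted over the list alone; 5.4e-05, or 0.163), and the placode list 0.81 with 6 of 23 risen (11 and 3 adjusted over the list alone; 4.0e-04, or 0.104). The BMP and TGF-β list, with a median of 0.89 and 2 of 19 risen (8 and 2 adjusted over the list alone), passed both ways (2.0e-04, and 0.0485 with an estimated correlation). Wnt/β-catenin targets had a median of 0.25, with Lef1, Lgr5 and Wif1 risen and Ascl2 fallen (0.0084, or 0.104). Wound and barrier stress genes had a median of 1.49 (6.8e-06, or 0.258), with Defb3 risen and 13 of 15 higher. Hair follicle keratins had a median of −0.61 (0.0348, or 0.509). The melanocyte list fell to a median of −2.33, with 7 of 9 genes lower adjusted over the list alone and none over all genes (2.0e-05, or 0.261), and sebaceous genes had −1.19 (8.2e-04, or 0.29). Immediate-early and dissociation stress genes, which sample handling also moves, had 0.71 with 16 of 17 higher (0.00152, or 0.48), and cell cycle genes −0.45 with all 29 lower (0.00897, or 0.778).

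Between SmoM2 stages no gene passed in limma. From 1 to 4 weeks 688 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.997, and without 1-week replicate 2, 24 genes passed, 12 in each direction. Leaving out 4-week replicate 3 left a single call in that comparison, Tmem267 (−3.60). All 29 cell cycle genes were lower at 4 weeks than at 1 week, with a median of −0.79 (camera adjusted p = 7.9e-12, or 0.474 with an estimated correlation). Interfollicular differentiation genes had a median of −0.62 (3.0e-04, or 0.497), immediate-early and dissociation stress genes 0.69 (3.0e-04, or 0.497) and bulge markers 0.54 (0.00252, or 0.497). The placode list had 0.33 (0.0497, or 0.405; 0.0505 with the block) and the BMP and TGF-β list 0.23 (0.0441, or 0.405). Sebaceous genes had a median of −0.94 (2.1e-05, or 0.405), and Krt36 and Krt84 differed by −2.76 and −2.74 (adjusted p = 0.997 for both). From 4 to 10 weeks 893 genes had an unadjusted p under 0.05, and the lowest adjusted p, 0.0523, was for Defb3 (3.72 ± 0.45). Without 4-week replicate 2, 13 genes passed, and without 4-week replicate 1 only Stap1 did (2.72). Wound and barrier genes had a median of 1.71 (1.9e-05, or 0.539) and interfollicular differentiation genes 0.44 (3.7e-04, or 0.613), with 14 of 15 and 22 of 27 higher at 10 weeks. Wnt/β-catenin targets had 0.27 (0.0165, or 0.291), leukocyte genes −0.59 (0.0137, or 0.613) and dermal fibroblast genes −0.34 (0.0429, or 0.539).

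The changes at 4 and at 10 weeks were measured against the same controls. Of the genes that rose, 57 were shared by the 349 at 4 weeks and the 81 at 10 weeks, against 1.98 for independent sets of this size, and of the genes that fell, 15 were shared by 114 and 19, against 0.152. Data simulated with no change and the same shared controls gave 0 shared calls in 100 runs, a value that too few calls fix in advance. With changes of the observed sizes placed on independent random genes, simulated data gave a mean of 1.98 shared rises (highest 5) and 0.59 shared falls (highest 3), from means of 388 and 81.8 calls. Across genes, which are not independent replicates, the changes at 4 and 10 weeks had r = 0.752 and a covariance of 0.291, against 0.446 and 0.0632 in simulated data without change. The changes at 1 and 4 weeks had r = 0.816 and 0.197, against 0.50 and 0.0632, and those at 3 days and 4 weeks r = −0.0417 and −0.0102, against 0.353 and 0.0633. These simulations left out the pairing of control, 1-week and 4-week arrays by number; with a correlation of 0.489 between paired arrays the simulated values were 0.317 and 0.032 for 4 and 10 weeks, 0.499 and 0.0322 for 1 and 4 weeks, and 0.252 and 0.0323 for 3 days and 4 weeks. Part of each overlap may come from the shared controls, which are too few to give each comparison 2 of its own.

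**Figure D3:**
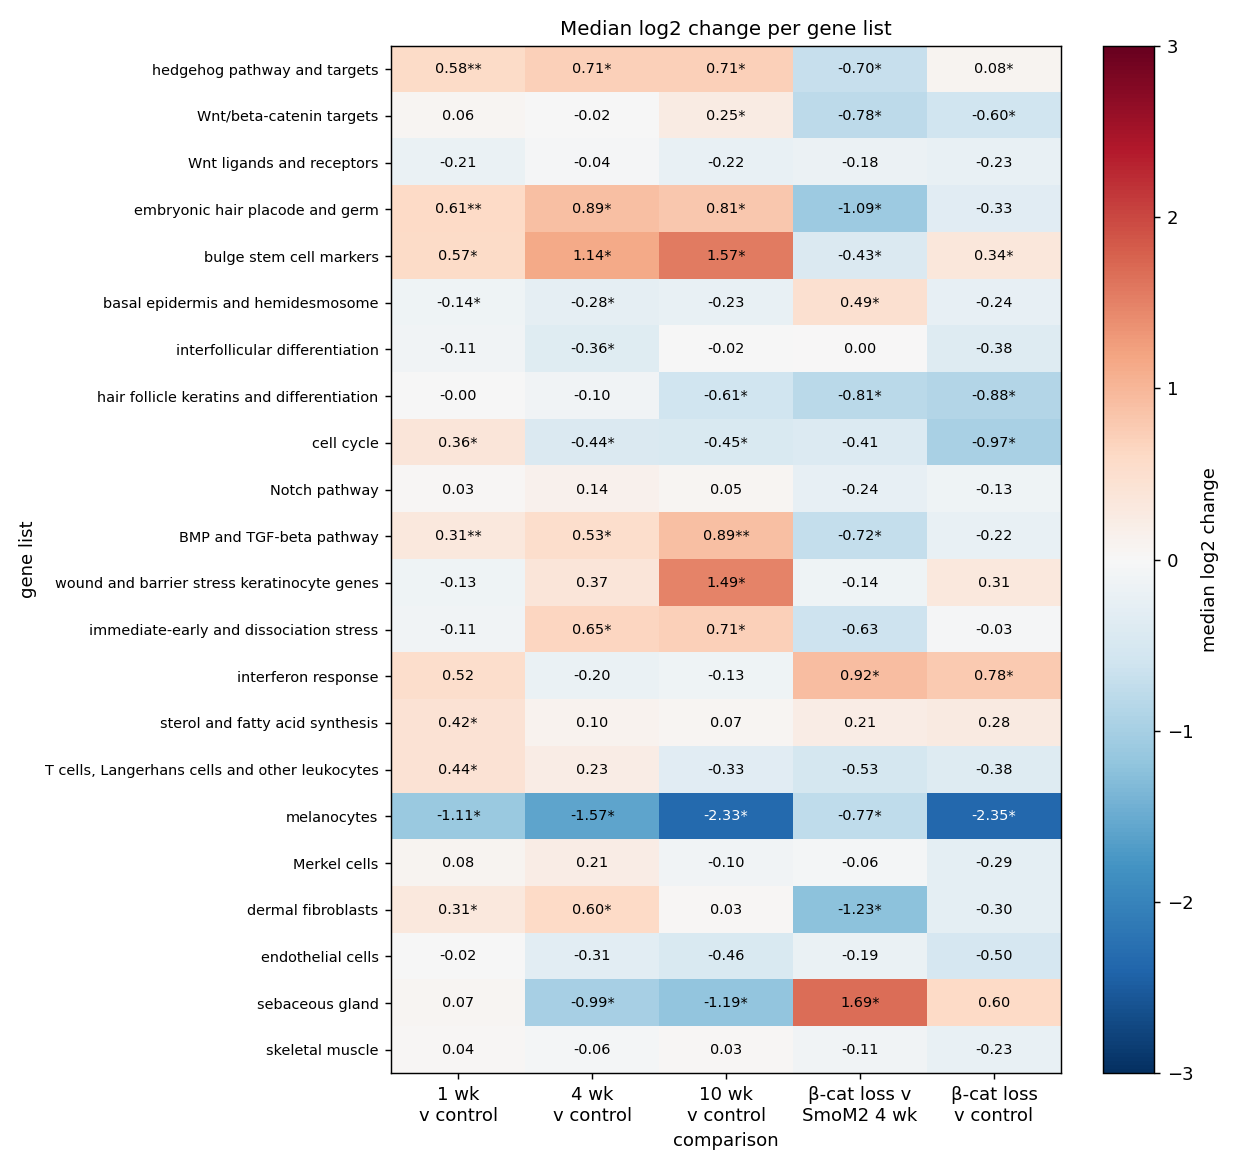
Median log2 change of each gene list (y axis) in 5 comparisons (x axis), as numbers on a colour scale from lower (blue) to higher (red). A single asterisk marks a camera adjusted p under 0.05, and a double asterisk a call that also held with an estimated correlation, as for the hedgehog list at 1 week (0.58).

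With β-catenin lost, many of the genes that SmoM2 raises were lower than in SmoM2 cells at the same time. Not all genes named next had passed as raised by SmoM2. Among those that had not at 4 or 10 weeks were Cux1, Tgfb2, Bmp7, Krt75, Krt35 and Scd2. Lef1 fell by 1.70 ± 0.21 (adjusted p = 0.00948; n = 2 and 3), to 5.58 against 5.92 in the controls. Wif1 changed by −6.25 ± 1.45 (adjusted p = 0.04997), to 3.53 from 9.77, the growth factor Tgfb2 by −4.47 ± 0.67 (0.0122), to 6.07 from 10.54, and the transcription factor Cux1 by −2.09 ± 0.33 (0.0148). Wif1 passed in 6 of 16 alternatives, and its signal under loss lay below the filter value of those arrays (4.91), so the size of its fall is uncertain. Pcdh20 changed by −4.47, Synpo2 by −4.87, Cdh11 by −3.97, the stem cell receptor Lgr6 by −4.09, the phosphatase Ptprv by −4.07 and Nrep by −4.23. Smaller falls were found for the follicle keratins Krt75 (−1.91) and Krt35 (−1.57), the desaturase Scd2 (−1.72) and the growth factor Bmp7 (−1.50).

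Other genes rose when β-catenin was lost. The ribonuclease Ang rose by 4.11 ± 0.54 (adjusted p = 0.0102), to 9.10 from 4.99. The cytokine receptor Il6ra rose by 3.89, the prostaglandin dehydrogenase Hpgd by 3.56, the glutathione transferase Gsta3 by 3.38, the growth factor Vegfd by 3.20, the decoy receptor Il22ra2 by 3.01, the thioesterase Acot5 by 2.98, the transporter Abcc3 by 2.68 and the hemidesmosome-associated integrin Itga3 by 1.23. The hedgehog genes were lower in value but did not pass: Gli1 −2.06 ± 0.60 (adjusted p = 0.0995), Ptch1 −1.44 (0.18), Hhip −4.02 (0.0852) and Smo −1.15 (0.0658). Gli1 had a signal of 7.22 in replicate 1 and 9.56 in replicate 2. Lgr5 (−2.93, 0.0716), Lhx2 (−2.46, 0.114) and Axin2 (−0.94, 0.184) did not pass either.

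In all, 318 genes differed between β-catenin loss and SmoM2 alone (144 with a covariate of Y-linked signal), 92 higher and 226 lower. The count was 147 without 4-week replicate 1 and 2 without β-catenin loss replicate 1, when Ang (5.16) and the helicase Ddx4 (3.45) passed. In the list tests placode genes had a median of −1.09, with 3 of 23 fallen (9 adjusted over the list alone; camera adjusted p = 9.7e-05, or 0.0535 with an estimated correlation). The BMP and TGF-β list had −0.72, with Bmp7 and Tgfb2 fallen (1 higher and 10 lower adjusted over the list alone; 4.6e-04, or 0.0535). Wnt/β-catenin targets had −0.78, with Lef1 and Wif1 fallen of 15 (1 higher and 6 lower adjusted over the list alone; 0.00659, or 0.0568). The hedgehog list had −0.70, with none past the threshold over all genes (2 higher and 6 lower adjusted over the list alone; 0.011, or 0.451). Bulge markers had −0.43 (0.0207, or 0.653), and hair follicle keratins −0.81, with Krt35 and Krt75 fallen (0.00827, or 0.492).

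Markers of other cells differed under β-catenin loss too. All 11 dermal fibroblast genes were lower, with a median of −1.23 and 5 lower adjusted over the list alone (4.6e-04, or 0.0568 with an estimated correlation), and melanocyte genes had a median of −0.77 (0.0289, or 0.666). Sebaceous gland genes were higher, with a median of 1.69 and 5 of 7 higher adjusted over the list alone, none over all genes (9.7e-05, or 0.232). All 12 interferon response genes were higher, with a median of 0.92 (0.00224, or 0.653), and basal epidermis genes had 0.49 with Itga3 risen (0.0207, or 0.451). Wound and barrier genes had a median of −0.14 but a mean of 0.46 and an upward test that did not pass (0.272).

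To ask how the SmoM2 changes as a group stood without β-catenin, genes were chosen at 10 weeks against control, so that the 4-week signals entered the choice only through the spread pooled over all IFE arrays, which moved the number of genes chosen when an array was left out. Of the 80 genes that rose at least 2-fold at 10 weeks, 73 were lower with β-catenin loss than with SmoM2 alone, 26 of them past the threshold over all genes. Their median change was −1.42 (camera adjusted p = 5.4e-27, or 0.0414 with an estimated correlation of 0.311), and against control their median was 0.50, compared with 1.76 for SmoM2 alone at 4 weeks. The 19 genes that fell had a median change of 0.06 between loss and SmoM2 alone, 8 of them lower and 11 higher, and stayed at −1.37 against control, compared with −1.80 for SmoM2 alone. The controls entered the choice and so push both values away from 0. With 80 and 19 genes chosen against 2 controls and measured against the third, the raised genes lay at 0.14 to 0.62 under loss, compared with 1.33 to 1.87 for SmoM2 alone, and the fallen genes at −0.77 to −0.76, compared with −1.44 to −0.86. Camera gave an adjusted p = 0.178 for the fallen set. Krt36 and Krt84 were lower still, by −1.95 and −1.99 (adjusted p = 0.347 and 0.246). The median of the genes that rose stayed between −1.70 and −1.04 with each array left out, past the threshold each time at the preset correlation. That of the genes that fell passed without 1-week replicate 2 or 3 or 4-week replicate 1 or 2, and reached at most 0.51. No gene was chosen at 1 week.

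**Figure D4:**
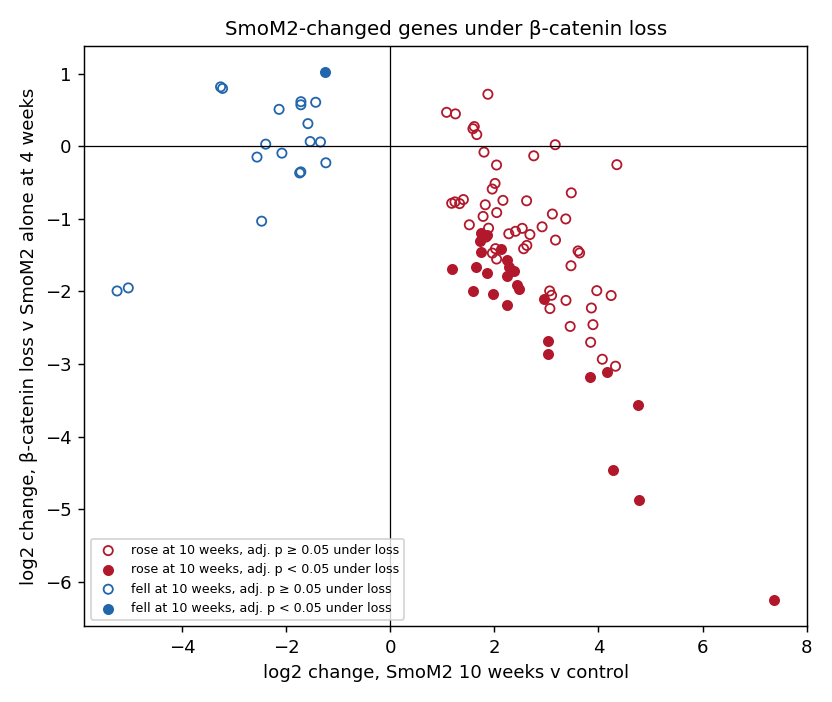
Log2 change between β-catenin loss and SmoM2 alone at 4 weeks (y axis) against log2 change at 10 weeks of SmoM2 against control (x axis) for the 80 genes that rose (red) and the 19 that fell (blue) at least 2-fold at 10 weeks. Each point is a gene, filled where the change under loss had an adjusted p under 0.05, and 73 of the red points lie below 0.

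Against untreated controls, cells with SmoM2 and without β-catenin had higher values of some hedgehog genes, none of which passed. Gli1 was 2.85 ± 0.60 higher (adjusted p = 0.0823; n = 2 and 3), Ptch1 2.65 ± 0.53 (0.0648) and Gli2 2.58 (0.083), and both arrays lay above all controls for Gli1 and Ptch1, while Hhip differed by −0.25 (0.932). The hedgehog list had a median of 0.08 and a mean of 0.49, with 10 of 16 genes higher and 3 of them adjusted over the list alone (camera adjusted p = 0.048, or 0.625 with an estimated correlation). Krt84 and Krt36 fell by 6.15 ± 0.83 and 6.11 ± 0.98 (adjusted p = 0.031 and 0.0346). The binding protein Igfbp3 changed by −4.18 ± 0.67 (0.0346), the mitochondrial transhydrogenase Nnt by −3.23 ± 0.45 (0.031), Nrp1 by −3.13, Hemgn by −2.53, Fam117a by −2.43 and Lyplal1 by −2.32. Rises were found for Ang (3.73), the amylase Amy1 (3.52), the vesicle tethering gene Vps52 (3.27), the epidermal cytochrome Cyp2b19 (2.68), Acot5 (2.65), the oviductal glycoprotein Ovgp1 (2.62 ± 0.31, adjusted p = 0.0143), Otud7a (2.53) and Ppil6 (2.51). Axin2 differed by −1.47 (0.1) and Lef1 by −0.33 (0.486).

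In all, 53 genes differed between β-catenin loss and control (11 with a covariate of Y-linked signal), 33 higher and 20 lower. After a further quantile normalization the split was 25 higher and 42 lower, with 44 of the 53 genes shared. The median change of all genes was −0.12 (−0.15 after quantile normalization), so gene values lie by that much lower on the scale. The count was 6 without control replicate 1, 9 without control replicate 2, 1 without control replicate 3 (Stk33, −3.29), 3 without β-catenin loss replicate 1 (Ang, Ddx4 and Cpxm1) and 54 without replicate 2. Melanocyte genes had a median of −2.35, with all 9 lower and 7 adjusted over the list alone (camera adjusted p = 8.2e-06, or 0.625 with an estimated correlation). All 29 cell cycle genes were lower, with a median of −0.97 (8.2e-06, or 0.625), hair follicle keratins had −0.88 with 2 fallen (6 adjusted over the list alone; 0.00349, or 0.625), and Wnt/β-catenin targets −0.60 with 3 of 15 lower adjusted over the list alone and none over all genes (0.0117, or 0.274). Interferon genes had 0.78 (0.00554, or 0.625) and bulge markers 0.34 (0.0117, or 0.625).

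In the bulge, the control array already had high signals of some genes that SmoM2 raised in the IFE, among them Gli1, Ptch1, Lhx2 and Lgr5, but not of others, with Wif1 at 4.70 and Fst at 6.06 against 4.83 and 8.10 in the IFE controls. Gli1 was 9.89 in the bulge control and 9.96 in bulge SmoM2 cells, and Ptch1 12.57 and 12.78, against 5.54 and 8.96 in the IFE controls. Lhx2 was 11.89 and 11.61, and Lgr5 11.62 and 10.34. Hhip was 7.67 and 10.64, and Wif1 4.70 and 9.89. The other largest differences upward were in the ribonuclease Rnase2b (5.17), the stress keratin Krt6b (5.06), the cornified envelope gene Rptn (4.52) and Ang (4.14). Those downward were in the Y-linked Eif2s3y (−4.23), the protease Adamts20 (−3.53), fibronectin Fn1 (−3.45), the smooth muscle actin Acta2 (−3.39) and Lrrc75b (−3.25). With an array per group there was no test: 622 genes were at least 2-fold higher and 370 lower in bulge SmoM2 cells.

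Among the lists in the bulge pair, wound and barrier stress genes had a median difference of 3.16, interfollicular differentiation genes 1.95 and hair follicle keratins 1.66, each at percentile 100 of 10000 random lists matched for signal. The random lists treat genes as independent. With a single array per group, the percentiles do not separate an array's own deviation from an effect of SmoM2. The hedgehog list had 0.14, at percentile 94.5 of the random lists, bulge markers −0.09, at percentile 7.36, and basal epidermis genes −0.44, at percentile 0. Leukocyte genes had 0.99 and dermal fibroblast genes 0.96, markers of other cells that moved with the same pair, and immediate-early and dissociation stress genes, which sample handling also moves, had 0.46 with 15 of 17 higher, all 3 at percentile 100. Interferon genes had 0.58 (percentile 99.99), Wnt/β-catenin targets 0.44 (99.98), BMP and TGF-β genes 0.39 (99.97), sebaceous genes 0.47 (99.3) and Merkel cell genes −1.03 (0.14).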

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

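The tests of the bulge arrays in this part were chosen only after their values were seen. Only the fixed set of named genes was searched for genes that differed between the tissues. For 8 of this set, the 3 IFE SmoM2 arrays at 4 weeks all lay on the same side of the 3 IFE controls. The bulge SmoM2 array lay on the opposite side of the bulge control. With a single array per bulge group, the difference between the tissues was not tested.

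Of the 8 genes Lgr5 and Lhx2 parted most, then Krt1. Lgr5 differed by −1.27 in the bulge and by 3.88 in the IFE, Lhx2 by −0.28 and 4.48, Cux1 by −0.58 and 1.10, Smo by −0.41 and 1.29, and Ctnnb1 by −0.025 and 0.51. The keratins went the other way: Krt1 differed by 2.05 in the bulge and −1.34 in the IFE, Krt10 by 0.93 and −0.94, and Krt14 by 0.083 and −0.86. The bulge control started from Lgr5, Lhx2 and Cux1 signals 5.21, 4.68 and 1.23 above the IFE controls and from Krt1 and Krt10 signals of −3.38 and −1.61 relative to them. After 4 weeks of SmoM2 some of the 8 lay close in both tissues: Lgr5 was 10.34 in the bulge and 10.28 in the IFE, Lhx2 11.61 and 11.69, Krt1 11.46 and 11.46, Krt14 13.27 and 13.27, and Ctnnb1 13.42 and 13.37. Others were further apart, with Krt10 at 13.20 and 12.94, Cux1 at 9.52 and 9.96 and Smo at 10.39 and 11.16, and outside the 8 so were Cd34, at 6.83 and 4.04, and Fst, at 7.04 and 9.65.

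The bulge control also had Gli1 and Ptch1 signals near those of SmoM2 cells. A technical explanation is that this array holds SmoM2-expressing cells, which its source label names. Over the 80 genes that rose in the IFE at 10 weeks, the bulge SmoM2 array lay above the bulge control by a median of 0.20 (bootstrap interval over genes 0.02 to 0.33), with 61.3% higher. The interval holds values on both sides of the 0.3 log2 set as the bound and treats genes as independent, so this explanation stays open, and so does normal hedgehog activity in the bulge, which was not tested. An exchange of the labels does not give this pattern, since the SmoM2 array lay at least 3.67 above the highest IFE control for Gli1 and Ptch1, so either array taken as the control is high. Whether the labels are right was not settled by this. Hhip, at 7.67 in the control and 10.64 in the SmoM2 array, and Wif1, at 4.70 and 9.89, differed in the direction of the labels. Genes that passed as raised in the IFE at 4 weeks went both ways. Lef1 (0.64) and Krt17 (0.38) were higher in the bulge SmoM2 array, and Lgr5 (−1.27) and Lhx2 (−0.28) lower. The bulge marker Cd34 lay at 9.72 and 6.83, but differed by only 0.14 in the IFE at 4 weeks, so it gives no direction.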

How the results depend on the processing

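The 9-array block, the Y-linked covariate and the run without sex chromosome genes were chosen after the data were seen. The lower signal of genes raised by SmoM2 under β-catenin loss (median −1.42) kept its direction and passed under all settings run with camera at the preset correlation, from −1.01 with the replicate block to −1.70 with an array left out; the estimated correlation was run for this set in the main fit alone. The bulge count of 992 stayed between 801 and 1019. Of the other values, 3278 of named genes stayed on their side of the threshold, 52 newly passed and 492 no longer passed, with no change of sign among genes that passed. Of list medians, 2699 stayed, 81 newly passed and 112 no longer passed. In the paired groups, beside the calls given in the report, the replicate block let Itga3 (adjusted p = 0.0462), Mc5r (0.0457) and Il33 (0.0448) pass at 4 weeks and took the placode list between 4 weeks and 1 week to 0.0505; it changed no other call of a named gene, or of a list under the main test. A pseudocount does not apply to log2 values, leaving out the lone array at 3 days gives no value, and without control replicate 3 too few genes fell at 10 weeks to give a median. What the signal over background limits was not measured apart from the filters.

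The cause was not tested for the following unless stated. With the replicate block, 2 genes changed at 1 week, 873 at 4 weeks, 163 at 10 weeks, 2 between 10 and 4 weeks (1810014B01Rik and Aknad1), 1347 between β-catenin loss and SmoM2 alone, and 169 against control. By experiment number the counts were 5 at 1 week (Gli1, Ptch1, Scarb1, Scnn1g and Sftpc), 856, 207, 1181 and 143 (0 between 10 and 4 weeks), and in the 9 arrays 9 at 1 week and 955 at 4 weeks. With array weights they were 1 at 3 days (Serpina12), 1545 at 10 weeks, 14 between 10 and 4 weeks, 102 and 96. With only the groups compared, where fewer samples set the spread, 738 changed at 10 weeks and 17 between loss and SmoM2 alone. With the Y-linked covariate 158 changed at 10 weeks, 144 between loss and SmoM2 alone and 11 between loss and control. Without the filter, with more genes tested, 59 changed at 10 weeks. The mean of probe sets gave 86 between loss and control. Quantile normalization, the stricter filter and the trend option each gave 1 between 10 and 4 weeks, Defb3. Genes that fell at 10 weeks, with a median of 0.06 under β-catenin loss, passed upward with only the groups compared (0.57), the replicate block (0.53), the experiment block (0.36), array weights (0.36) and the Y-linked covariate (0.69).

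With an array left out, counts ranged from 0 to 50 at 1 week, 13 to 410 at 4 weeks, 0 to 45 at 10 weeks, 0 to 24 between 4 weeks and 1 week, 0 to 13 between 10 and 4 weeks, 2 to 247 between loss and SmoM2 alone, and 1 to 54 between loss and control, and stayed 0 at 3 days. The median of genes that fell ranged from −0.034 to 0.51. List tests turned round in a few settings: immediate-early genes at 3 days had 0.56 with the experiment block. For the lone array at 3 days the replicate block ended 3 list calls and added 1. In the groups not taken as paired it ended the calls of hair follicle keratins (0.111) and cell cycle genes (0.199) at 10 weeks, of hair follicle keratins (0.0546), basal epidermis (0.0771) and melanocytes (0.124) between loss and SmoM2 alone, and of the hedgehog list between loss and control (0.139), where it added wound and barrier genes (0.0356). Between 10 and 4 weeks immediate-early and dissociation stress genes ranged from −0.50 without 4-week replicate 1 to 0.46. Cell cycle genes in that comparison ranged from −0.34 without 4-week replicate 2 to 0.30. Between loss and SmoM2 alone, cell cycle genes had 0.31 without β-catenin loss replicate 1 and −1.08 without replicate 2.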

Other observations

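The tests of dilution and of replicate 1 in this part were chosen only after the result was seen; the splits and the neighbour test were set out before theirs. Genes raised and genes fallen at 10 weeks stood differently under β-catenin loss, a difference that was not itself tested. Against a control left out of their choice, the raised genes kept 9.11% to 33.4% of their median rise at 4 weeks and the fallen genes 52.4% to 87.8% of their median fall, over the 3 controls. Wif1, a secreted Wnt antagonist, lay at 4.83 in the controls, 9.77 at 4 weeks and 12.21 at 10 weeks, and at 3.53 without β-catenin. Its control and loss means lay below the filter values of those arrays (4.88 to 4.99 and 4.91), so they do not tell these groups apart. Lef1 lay at 5.92, 7.28 and 7.10, and at 5.58 without β-catenin. Tgfb2 lay at 8.25, 10.54 and 11.36, and at 6.07 without β-catenin, while Gli1 at a mean of 8.39 was nearer to its SmoM2 level of 10.44 than to the control level of 5.54, with 7.22 in replicate 1 and 9.56 in replicate 2.

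The median of the melanocyte list was lower in every IFE SmoM2 group, a call that held in none of them with an estimated correlation. In the bulge control these genes already lay at a median of −2.30 relative to the IFE controls, so the bulge pair (0.17) says little about them. Dct, a melanin synthesis enzyme, lay at 9.89 ± 1.34 (SD, n = 3) in the controls, 8.56 at 1 week, 8.17 at 4 weeks, 6.88 at 10 weeks and 5.69 under β-catenin loss, and Tyrp1 at 9.21, 7.74, 6.63, 6.09 and 4.71. S100a8, a neutrophil and wound keratinocyte gene, lay at 7.99 ± 2.31 (SD) in the controls and 12.72 ± 0.45 at 10 weeks, with 10.66 in control replicate 3. None of these passed over all genes, and whether the sort removed melanocytes and wound keratinocytes was not tested.

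Whether the lower signal of raised genes under β-catenin loss may come from cells that did not recombine was tested with the fallen genes. If the loss arrays were a mixture with control cells, the fallen genes would return nearly to the control level. Genes chosen against 2 controls were measured against the third, since the controls of the choice make fallen genes look lower. The raised genes would then put the SmoM2 cells at 5.44% to 20.4%, and the fallen genes would lie at −0.14 to −0.042. The highest of their 3 medians was −0.76 (bootstrap interval over genes −1.19 to −0.38). All 3 intervals lay below the diluted value, the nearest reaching −0.20, so these genes lay lower than dilution alone would put them. Whether β-catenin loss itself lowers them cannot be told, since no group had loss without SmoM2, so dilution of the raised genes is not excluded. The intervals treat genes as independent and each rests on a single control array. Under some alternatives the fallen genes lay 0.36 to 0.69 above the SmoM2 arrays, so a partial dilution stays open. In its probe set of highest mean, Smo lay at 9.87 in the controls, 11.16 at 4 weeks and 10.00 under loss, near control. Gli1 returned less far, with 5.54, 10.44 and 8.39. The labels name the sorted cells as SmoM2-positive, which would leave out cells without SmoM2; how well the sort did so was not tested.

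A lower signal in replicate 1 alone was also tested, since Gli1 lay at 7.22 in it and 9.56 in replicate 2. Over the 80 raised genes replicate 2 by itself lay at −1.30 (interval −1.53 to −0.97) against the SmoM2 arrays and replicate 1 at −1.55, so the lower median is not in replicate 1 alone. The interval is over genes and gives no spread between samples. Calls of single genes leaned far more on replicate 1 than on replicate 2. Leaving out either leaves a single array in the group. What stays open is a need of these genes for β-catenin, which the design names. An effect of the loss by itself stays open too, since no group had loss without SmoM2. So do differences in strain background, breeding or day between the mice, which the group cannot be told apart from. Differences in sex, for which the groups were not balanced, stay open as well. A biological reading remains a hypothesis found in these data.

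Nnt, a gene that some laboratory mouse strains lack in part, lay at 6.43 ± 1.33 (SD, n = 2) in the β-catenin loss arrays and at 9.65 ± 0.28 (SD, n = 3) in the controls. A candidate explanation for part of the 53 genes that differ from control is a block of chromosome from another strain. Among them 2 pairs lay within 10 tested genes of each other, against a median of 2 in 2000 random sets, most of which held 0 to 5. The bound written for excluding this, a count at or below the random median, was too loose: random sets reach down to 0 pairs, so a low count cannot exclude it, and the test leaves it open.

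With 3 arrays against 3 there are 10 splits, so no share of splits can be under 0.05. For 4 weeks against control, 1 of the 10 splits gave as many genes as the real 463, and the highest of the others, which include 3 that part all the numbered pairs as the real split does, gave 0. For 1 week against control all 10 splits gave the real count of 0 or more, with a highest other of 0. For 4 weeks against 1 week all 10 splits gave 0 or more, with a real count of 0 and a highest other of 14, and the 3 others that part all pairs gave 0, 3 and 0.

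Probe sets without a gene name were left out of the report. At 4 weeks against control 4463 of them were tested by themselves, and in limma 0 changed, with 355 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0992. With all 31183 probe sets above the filter tested together 305 changed, 7 of them without a name.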
